A study of Mus musculus with 24 samples.

How the data were processed

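RNA from mouse cortex was sequenced in 24 libraries, 6 in each of 4 groups. Untreated libraries of wild-type (WT) mice and of mice labelled 5xFAD measured genes, and libraries treated by A-tailing and RNase R measured circular RNAs (circRNAs). Per the labels' protocols, total RNA was polyadenylated and digested with RNase R, an exonuclease that degrades linear RNA, ribosomal RNA was depleted, and libraries were prepared with a kit from NEB. The series text names ages of 5 and 7 months, but no label or column gives the age of a single library, so no age was assigned and no comparison between ages was made. The titles number the libraries of each table from 7 to 18. Numbers 7 to 12 and 13 to 18 each hold 3 WT and 3 5xFAD libraries and were fitted as a run term, called run 7-12 and run 13-18. Whether these runs hold the ages named in the series text is not stated for any library, so a difference between the runs can be one of batch, of age or of both. The names of both deposited tables list WT and 5xFAD at 5 months before WT and 5xFAD at 7 months, and the columns run from number 7 to 18 in blocks of 3 WT and 3 5xFAD libraries, an order in which run 7-12 would hold the younger mice; order alone was not used to assign an age. No label states that each library came from a separate animal, and p-values then measure only the spread between these libraries.

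The gene table lists 24318 gene symbols with values read here as FPKM. The authors deposited them without a unit in the header, and FPKM was inferred from the decimal values, the unequal column sums and Cuffdiff, which the submitters' processing notes name together with TopHat2 2.1.0 and the mouse genome build mm9. The annotation is not given in the sources used here. No read counts were used for this table, so its depth is unknown. FPKM summed to between 382920 and 572713 per library, and 4648 symbols were listed at 0 in every library. An exact 0 in this table can be a failed estimate, since Malat1 and Rn45s, among the highest values elsewhere, were listed at 0 in some libraries.

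The circRNA table lists 455928 back-splice junctions by mm9 position with a normalized signal. The deposited signal had been scaled by the authors so that every library sums to 81099.3, a step inferred from the values, and the circRNA caller is not given in the sources used here. Whole reads were recovered: 100% of the 687228 values above 0 were whole multiples of the value of 1 read in their library, within 0.001 of a read. Back-spliced reads per library ranged from 432246 to 1196931. Of the junctions, 221253 were listed at 0 in every library and 38535 were seen in at least 6 libraries, which held 93.1% of the reads. Reads are not independent molecules, so floors and intervals from them cover counting error only. Starts were converted from 0-based to 1-based. The reference at hand was GRCm38, another build: only 2.33% of starts and 2.30% of ends of the 3000 most abundant circRNAs lay at its exon borders, and the last junction on chromosome 1 ended at 196989781, past its last exon at 195323493. No host genes were therefore assigned, and neither host gene lists nor a comparison of circRNAs with their host genes was run.

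Genes were tested with limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend) on log2(FPKM + 1), for the 13676 genes with at least 1 FPKM in at least 3 libraries. Fold changes are on that scale and understate the change of low genes. The overall comparison had terms for genotype and run over all 12 untreated libraries. Comparisons within a run, and the difference between them, were contrasts of 4 group means in 1 fit. CircRNAs were tested in the same way on log2(value + 0.0921), the median value of 1 read, for the 38535 seen in at least 6 libraries. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. edgeR 4.0.16, DESeq2 1.42.0 and limma voom were run on the recovered reads as alternatives. Library totals were compared by exact 2-sided permutation tests. These choices, and 23 gene lists with 324 genes, of which 319 are in the table, were made before the data were examined. The tests on recovered reads, the median-of-ratios scaling of circRNAs, the sets of circRNAs that share a back-splice end, the thinning of libraries to equal reads, the term for chromosome Y reads, the removal of the length trend, the omission of genes listed at 0 and the gene families named in the other observations were added afterwards. The families of respiratory chain, ribosomal protein and histone genes were chosen after some of their members had been seen among the calls. A further family, of nuclear noncoding RNAs, was assembled and tested in the same way and then dropped, because its members had been picked from the calls themselves; only its genes are reported. A comparison of libraries with and without chromosome Y reads was also run and dropped, because it formed groups from measured values.

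Lists with at least 5 tested members were tested with camera at its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The lists cover disease-associated and homeostatic microglia, complement, antigen presentation, interferon response, lysosome, reactive and baseline astrocytes, myelin, oligodendrocyte precursors, endothelium and pericytes, excitatory and inhibitory neurons, synapses, activity-regulated genes, striatum, choroid plexus, blood, sex-linked genes, circRNA factors, circRNA hosts of brain, orthologs of Alzheimer risk genes, and genes related to the transgenes.

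Genes are named by rule: among calls whose groups do not overlap, the 10 largest rises and the 10 largest falls, and the 4 members of each list with the smallest p. Where no circRNA passed, the 5 with the smallest p are named, and the 10 most abundant circRNAs are named in any case. Results of some genes that the rule selects are not reported here. Transcript lengths were summed exon lengths from the reference annotation, matched by symbol for 99.2% of tested genes. Near-identical genes (histones, Bcl2a1 and H2 genes) can share reads, and the authors' counting could split these, so their values are uncertain. It is not stated whether counting used strand, so antisense genes are uncertain too.

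On simulated data for the overall gene comparison, 78% of genes changed by a log2 of 0.5 and 97% of those changed by 1 were recovered among 13676 genes, with 7 false calls. For the circRNA comparison over 35229 junctions, limma recovered 26% of 2-fold and 100% of 4-fold changes among the 1000 most abundant, and 2% and 14% among the rest. edgeR recovered 26% and 100% of them, and 4% and 18% of the rest, over 23725 junctions. The simulated noise was independent between genes and between circRNAs, without structure shared across a library. Recovery and false calls in the real data can therefore differ from these shares. No 2 libraries were duplicates: the smallest chi-square between any pair over abundant circRNAs was 4.85 per degree of freedom. Back-spliced reads from chromosome Y and Y-linked genes were found in the same 4 title numbers in both tables (7, 12, 13 and 16), 2 WT and 2 5xFAD. WT and 5xFAD libraries share no title number, so no pairing was used. Alternatives covered pseudocounts, filters, scalings, the mean trend, library weights, the run term, single runs, each library left out in turn, and the added settings above. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 prepared the tables, and matplotlib 3.10.9 drew the figures.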

Results

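RNA of the cortex was compared between wild-type (WT) mice and littermates labelled 5xFAD, a line with transgenes under the Thy1 promoter that carry mutations of familial Alzheimer disease. Genes were measured in 12 untreated libraries and circRNAs in 12 libraries treated with RNase R, 6 per genotype. The depth of the gene libraries is unknown, with 17270 to 17902 genes above 0 per library. Back-spliced reads numbered 432246 to 1196931 per circRNA library. Values are means ± SD in FPKM for genes and in normalized signal for circRNAs, and changes are log2 of 5xFAD over WT with the standard error (SE) and limma's 2-sided adjusted p.

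Thy1, whose promoter drives the transgenes, rose from 316 ± 16.9 to 704 ± 211 FPKM (n = 6 each), a log2 change of 1.07 (SE 0.21, adjusted p = 0.0342). It lay at 717 to 831 FPKM in 5 of the libraries labelled 5xFAD and at 284 FPKM in the untreated replicate 6, below every WT library (286 to 332). Mouse App measured 556 ± 26.9 FPKM in WT and 536 ± 30.1 in 5xFAD, a log2 change of -0.05 (adjusted p = 0.616) that turned to 0.065 with quantile normalization. Transgene transcripts were not measured apart from the mouse genes.

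Whether the transgenes come with a change of cortical gene expression was tested over both runs. Some genes of microglia and of innate immunity were among the rises called in 5xFAD cortex. Clec7a, the gene of the receptor dectin-1, rose from 0.0995 ± 0.0497 to 4.10 ± 2.56 FPKM, a log2 change of 1.98 (SE 0.365, adjusted p = 0.0302, n = 6 each). C4b, a complement component, rose from 5.32 ± 0.491 to 15.2 ± 8.52 FPKM (log2 1.20, SE 0.27, adjusted p = 0.0423), and Ly86, which encodes a partner of a toll-like receptor, from 6.35 ± 0.512 to 15.5 ± 5.74 FPKM (log2 1.08, adjusted p = 0.0302). Bcl2a1b, a survival gene of the BCL2 family with near-identical neighbours that can share reads, rose from 0.655 ± 0.223 to 3.09 ± 1.16 FPKM (log2 1.27, SE 0.161, adjusted p = 0.0109), the smallest adjusted p of the comparison. The macrophage gene Mpeg1 rose by 1.17, the MHC class I gene H2-Q4, whose reads can be shared with its paralogs, by 0.87, and Rsc1a1, 4930563F08Rik, Tmem181b-ps and Fam46c by 1.05, 1.03, 0.92 and 0.86. In each of these 10 genes all 6 libraries labelled 5xFAD lay above all 6 WT libraries. The genes were named by that rule, so this is no further support for their rise.

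The 10 largest falls without overlap between the genotypes were smaller. Btbd17 fell by 0.52, Tusc1 by 0.48, the histone gene Hist1h2bg by 0.46, Creld2 by 0.39, Ap1s1 by 0.36 and Tmem261 by 0.34. The other 4 encode parts of the mitochondrial respiratory chain: Ndufc2 fell from 127 to 94.3 FPKM (log2 -0.43, adjusted p = 0.0406), Ndufc1 from 88.1 to 66.0 (log2 -0.42, adjusted p = 0.0296), Ndufs7 by 0.37 and Sdhb from 84.9 to 66.2 (log2 -0.36, adjusted p = 0.0315). With quantile normalization 23 genes rose and 1 fell.

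Of 13676 genes tested by limma, 277 rose and 104 fell over both runs, and 3235 had an unadjusted p under 0.05. The count of 381 rested on single libraries. Without WT replicates 1 to 6 in turn it was 8, 3, 4, 1033, 26 and 3, and without 5xFAD replicates 1 to 6 it was 6, 3, 3, 97, 8 and 977.

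**Figure D1:**
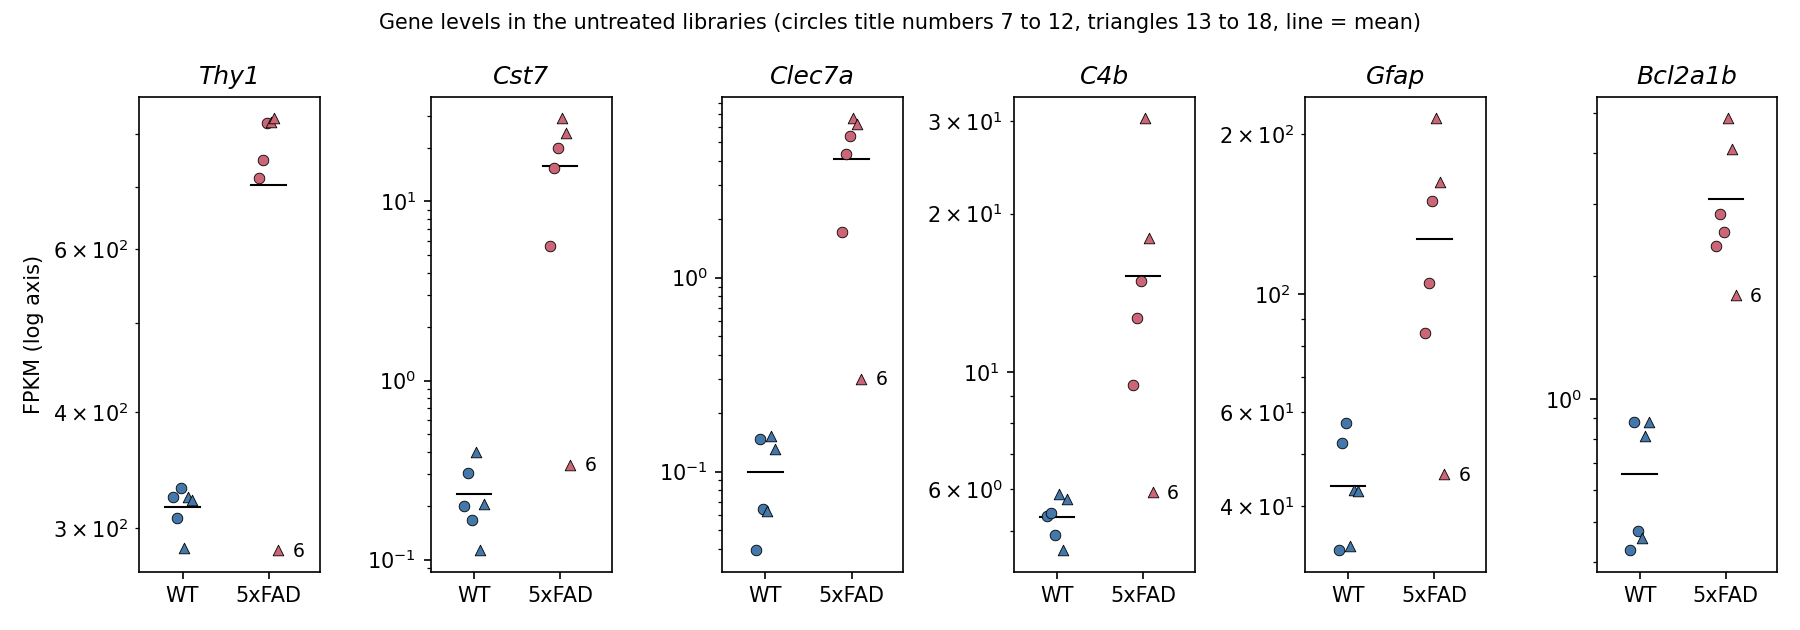
FPKM of Thy1, Cst7, Clec7a, C4b, Gfap and Bcl2a1b on a log axis in each untreated library, by genotype; circles are title numbers 7 to 12, triangles 13 to 18, lines are group means and the digit marks 5xFAD replicate 6. Thy1 lies at 284 FPKM in replicate 6 and at 717 to 831 in the other 5 libraries labelled 5xFAD.

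Microglial lists moved up as sets in 5xFAD cortex. Of 28 tested genes of disease-associated microglia, the state of microglia near amyloid plaques, 11 rose (17 adjusted over the list alone), with a median log2 change of 0.69 (camera adjusted p = 1.84e-10; adjusted p = 0.266 with an estimated correlation). Cst7, a cystatin, rose from 0.231 ± 0.104 to 15.7 ± 11 FPKM (log2 3.23, SE 0.61, adjusted p = 0.0302), the chemokine gene Ccl6 by 1.73 and Tyrobp, the adaptor of TREM2, from 23.3 ± 4.33 to 60.6 ± 24.8 FPKM (log2 1.23, adjusted p = 0.0406). Trem2 itself had a log2 change of 1.20 and missed the threshold (adjusted p = 0.0572). Of 16 homeostatic microglial genes 2 rose (11 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 3.04e-06; adjusted p = 0.266 with an estimated correlation). Laptm5 rose by 0.81 and Olfml3 by 0.63, while Csf1r at 0.43 did not pass (adjusted p = 0.0611).

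Further lists of innate immunity and of degradation moved the same way. Among 14 interferon genes 4 rose (13 adjusted over the list alone; median 0.64, camera adjusted p = 5.66e-10; adjusted p = 0.266 with an estimated correlation), among them Cxcl10 at 0.75, Irf7 at 0.58 and Stat2 at 0.40. Among 9 complement genes 3 rose (8 adjusted over the list alone; median 0.60, camera adjusted p = 3.04e-06; adjusted p = 0.266 with an estimated correlation), C4b, C3ar1 at 0.72 and Itgb2 at 0.74; Itgam at 0.46 did not pass (adjusted p = 0.0548). Among 11 antigen presentation genes B2m rose from 74.2 to 135 FPKM (log2 0.81) and was the only call (6 adjusted over the list alone; median 0.28, camera adjusted p = 6.82e-04; adjusted p = 0.406 with an estimated correlation), with H2-K1 at 0.66, H2-D1 at 0.73 and Psmb8 at 0.68 short of it (adjusted p = 0.0596, 0.0812 and 0.0596). Among 20 lysosomal genes 6 rose (11 adjusted over the list alone; median 0.25, camera adjusted p = 1.25e-07; adjusted p = 0.266 with an estimated correlation), among them the enzyme gene Gusb (0.62) and the progranulin gene Grn (0.57).

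Lists of reactive astrocytes, vessels, risk genes and inhibitory neurons also passed by camera at its preset correlation. Among 10 reactive astrocyte genes 3 rose (5 adjusted over the list alone; median 0.25, camera adjusted p = 0.00157; adjusted p = 0.266 with an estimated correlation), including Gfap, the intermediate filament of astrocytes, from 43.6 ± 9.75 to 127 ± 60.6 FPKM (log2 1.39, SE 0.30, adjusted p = 0.0419, n = 6 each), and Osmr by 0.62. Among 13 endothelial and pericyte genes 2 rose (9 adjusted over the list alone; median 0.37, camera adjusted p = 3.30e-06; adjusted p = 0.266 with an estimated correlation), Pecam1 by 0.67 and Ly6c1 by 0.86, with Flt1 at 0.83 and Tek at 0.52 short of the threshold (adjusted p = 0.0634 and 0.0606). Among 16 orthologs of Alzheimer risk genes Inpp5d rose by 0.57 and Cd2ap by 0.40 (4 adjusted over the list alone; median 0.07, or 0.04 without 5xFAD replicate 5; camera adjusted p = 0.0361; adjusted p = 0.406 with an estimated correlation), and Cd33 had 0.53 (adjusted p = 0.0646). The list of 11 inhibitory neuron genes had a median of -0.20 (camera adjusted p = 0.0311; adjusted p = 0.266 with an estimated correlation) with 0 calls by limma over all genes and 1 fall adjusted over the list alone. Sst, the gene of somatostatin, measured 335 ± 26.9 FPKM in WT and 253 ± 46.7 in 5xFAD (log2 -0.42, adjusted p = 0.0576), and Npy, Vip and Slc32a1 had changes of -0.18, -0.27 and -0.31. The striatal list differed widely between libraries. Relative to the WT mean it was -1.13 and -1.43 in 5xFAD replicates 3 and 5, where the inhibitory list was -0.32 and -0.37. It was 0.96 and 0.86 in replicates 2 and 6, where the inhibitory list was -0.06 and 0.06. In 5xFAD replicate 1 the striatal list was -0.06 and the inhibitory list -0.33. They were -0.58 and -0.21 in 5xFAD replicate 4, and -1.21 and -0.03 in WT replicate 5.

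For the microglial, complement, interferon, lysosomal, antigen, reactive astrocyte and endothelial lists, the median stayed above 0 without any 1 library, between 0.56 and 0.85 for disease-associated microglia. Call counts over all genes moved with the libraries as given above. Without the untreated 5xFAD replicate 6, 16 genes of disease-associated microglia, 8 of homeostatic microglia, 12 interferon, 8 complement, 4 antigen presentation, 9 lysosomal, 4 reactive astrocyte and 4 endothelial genes rose.

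The remaining lists did not pass. Median changes were -0.05 for 12 baseline astrocyte genes (camera adjusted p = 0.642), 0 for 14 myelin genes (0.793), 0.06 for 7 oligodendrocyte precursor genes, whose mean was -0.01 (0.945), 0 for 12 excitatory neuron genes (0.945), 0.01 for 28 synaptic genes (0.945), -0.19 for 13 activity-regulated genes (0.407), -0.22 for 10 striatal genes (0.502), 0.11 for 6 blood genes (0.378), 0.03 for 5 sex-linked genes (0.945), 0.02 for 15 circRNA factors (0.378) and 0.05 for 21 circRNA hosts of brain (0.6). In these lists limma called 0 genes over all genes, and adjusted over the list alone only 1 blood gene rose. The medians of baseline astrocytes and oligodendrocyte precursors changed sign with quantile normalization, and those of oligodendrocyte precursors and activity-regulated genes with array weights. Single libraries moved these medians: striatal genes from -0.54 without 5xFAD replicate 6 to 0 without replicate 3, activity-regulated genes from -0.37 without 5xFAD replicate 5 to -0.04 without replicate 3, blood genes from 0.05 without 5xFAD replicate 5 to 0.30 without replicate 4, sex-linked genes from -0.54 without 5xFAD replicate 4 to 0.55 without WT replicate 4, and oligodendrocyte precursors to -0.05 without WT replicate 1. The medians of the other lists in this group lay between -0.09 and 0.07 without any 1 library. Choroid plexus genes had too few tested members for a list test: Ttr, a carrier of thyroid hormone, measured 341.6 FPKM in WT replicate 3 and 169.1 in 5xFAD replicate 2, and its change of 0.54 had an adjusted p of 0.77. Without 1 library this change ranged from 0.064 to 1.363. The list related to the transgenes, also too small for a test, includes Thy1 and App as given above.

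**Figure D2:**
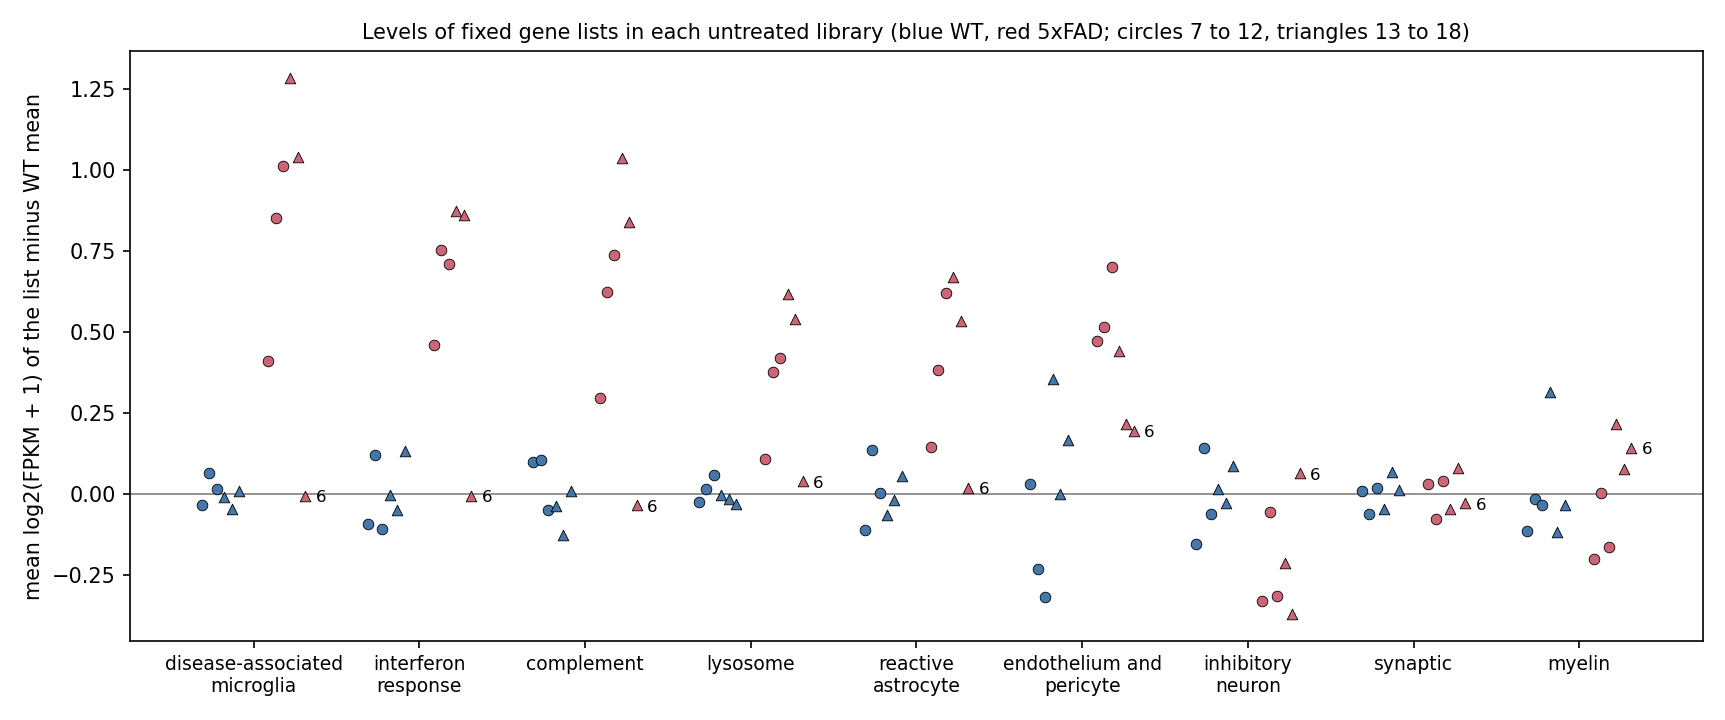
Mean log2 level of 9 gene lists in each untreated library, minus the WT mean, by genotype; circles are title numbers 7 to 12 and triangles 13 to 18. The list of disease-associated microglia has a median log2 change of 0.69.

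Within run 7-12, with 3 libraries per genotype, genes of blood vessels were among the largest rises. Flt1, a receptor of VEGF, rose by 1.53, the endothelial genes Ly6c1 by 1.45, Adgrf5 by 1.42 and Ptprb by 1.31, and Pecam1 by 1.10 (adjusted p = 0.00715 for all but Ptprb at 0.00968). Ccl6 rose by 1.90, H2-Q4 by 1.31, and the little studied transcripts 9530091C08Rik, 4930563F08Rik, 4930447F24Rik and Ppp2r2cos by 1.39, 1.37, 1.33 and 1.31. Histone genes led the falls: Hist1h2ac fell by 1.32, Hist1h2ai by 1.15, Hist1h4k by 1.11, Hist1h3a by 0.96 and Hist1h4a by 0.87, all of them near-identical to other histone genes. LOC100504703, 0610040B10Rik, Ppp1r35, 1810043H04Rik and Tpgs1 fell by 1.22, 1.06, 0.89, 0.85 and 0.85. The list of 13 endothelial genes had a median of 0.64 with 6 rises (10 adjusted over the list alone; camera adjusted p = 1.65e-09; adjusted p = 0.433 with an estimated correlation). The 14 interferon genes had a median of 0.66 (2 rises, 10 adjusted over the list alone; camera adjusted p = 1.40e-06; adjusted p = 0.609 with an estimated correlation). Disease-associated microglia had a median of 0.61 (1 rise, 6 adjusted over the list alone; camera adjusted p = 8.93e-05; adjusted p = 0.609 with an estimated correlation).

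In total 402 genes rose and 243 fell in run 7-12, with 3288 at an unadjusted p under 0.05, and 53 passed when the run was fitted alone. Quantile normalization gave 247 rises and 76 falls. Without WT replicates 1 to 3 the count of 645 became 343, 20 and 428, and without 5xFAD replicates 1 to 3 it became 88, 332 and 15.

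Within run 13-18 limma called 2 genes, with 596 at an unadjusted p under 0.05, and neither call is a measured change. Malat1 was listed at 0 in 5xFAD replicates 4 to 6 and lay between 1538 and 4333 FPKM elsewhere, and Rn45s was listed at 0 in WT replicates 4 to 6 and lay between 2332 and 3598 elsewhere. With genes listed at 0 throughout a group of a run left out, limma called 0 genes (593 at an unadjusted p under 0.05), and without the untreated 5xFAD replicate 6 it called 53 or, without replicate 4, 3. Genes of disease-associated microglia had a median of 0.74 (0 rises over all genes, 13 adjusted over the list alone; camera adjusted p = 7.50e-19; adjusted p = 0.12 with an estimated correlation), complement genes 0.80 and lysosomal genes 0.33 (0 rises over all genes, 7 and 10 adjusted over the list alone; camera adjusted p = 1.83e-10 and 1.90e-16; adjusted p = 0.12 with an estimated correlation for both). Without 5xFAD replicate 4 the microglial median was 0.45 and the complement median 0.53, and without replicate 6 the microglial median was 1.12. Endothelial genes had 0.13 (camera adjusted p = 0.0603), which was 0.03 without WT replicate 5 and 0.20 without WT replicate 4.

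The difference between the runs, which can be one of batch, of age or of both, was tested directly. Endothelial genes had a smaller effect in run 13-18: the median difference was -0.55 (camera adjusted p = 1.28e-12; adjusted p = 0.221 with an estimated correlation), and all 13 members were lower. Single vascular genes did not pass, with adjusted p = 0.39 for Flt1 (1.53 and 0.13 in the runs) and 0.673 for Ly6c1 (1.45 and 0.26). Activity-regulated genes differed by 0.66 the other way, or by 0.32 without 5xFAD replicate 5 (camera adjusted p = 7.47e-05; adjusted p = 0.95 with an estimated correlation). Disease-associated microglia differed by a median of 0.07 (camera adjusted p = 0.394). Without 1 library this ranged from -0.08 without 5xFAD replicate 4 to 0.40 without replicate 6. Of single genes only Malat1 and Rn45s were called, from their values listed at 0, and without such genes limma called 0 (621 at an unadjusted p under 0.05). Across genes, which are not independent replicates, the effects of both runs had Pearson's r = 0.418 and Spearman's rho = 0.568, and 71.6% of all 13676 genes and 94.7% of the 645 calls of run 7-12 had the same sign in run 13-18. These genes include Malat1 and Rn45s with their values listed at 0. Among the 1000 genes of highest mean level r was 0.043 and rho 0.61.

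Library totals of circRNAs were compared between the genotypes. Back-spliced reads depend on how deeply each library was sequenced, and no other read total was used. These totals therefore cannot tell whether 5xFAD cortex holds more or fewer circRNAs. Libraries labelled 5xFAD detected 52728 circRNAs on average and WT libraries 61810 (exact 2-sided permutation p = 0.169, n = 6 each, 924 splits). The back-spliced reads behind them numbered 764900 ± 276100 and 978690 ± 181900 (exact permutation p = 0.145). Thinned to 432246 reads per library, 44076 and 46416 circRNAs were detected (exact permutation p = 0.446). The 20 most abundant circRNAs held 8.39% and 8.46% of the reads (exact permutation p = 0.755). Within each run no p was below 0.1, the smallest that 20 splits can give, and adjusted over the 21 tests of this family none was below 0.624.

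Single circRNAs were compared next, by position in mm9. The most abundant, at chromosome 1, 89260679 to 89276583, held 134625 reads and measured 1053 ± 112 in WT and 1011 ± 203 in 5xFAD (log2 -0.07, 95% interval -0.32 to 0.17, n = 6 each). Among the 1000 most abundant circRNAs, 956 had a 95% interval that lay within 2-fold in either direction and so excluded a larger change, and the median half-width was 0.45 on the log2 scale. Of all 38535 tested 4377 had such an interval, and for the others a 2-fold change was not excluded with these libraries.

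The 5 circRNAs with the smallest p missed the threshold. The circRNA at chromosome 2, 77468418 to 77504684 measured 17.6 ± 7.56 in WT and 37.5 ± 16.1 in 5xFAD (log2 1.06, SE 0.24, adjusted p = 0.554). The circRNA at chromosome 10, 31583428 to 31583670 had a change of 1.08, and that at chromosome 9, 44721304 to 44722894 one of -2.08. At chromosome 19, 45883760 to 45884943 all 6 libraries labelled 5xFAD lay above all WT libraries (2.75 ± 1.14 and 0.683 ± 0.449, log2 2.03). The circRNA at chromosome 9, 43855868 to 43856381 was listed at 0 in all WT libraries but replicate 3, where it measured 0.0918. It was also listed at 0 in 5xFAD replicate 6. limma called 0 of the 38535 (1474 at an unadjusted p under 0.05), and edgeR, DESeq2 and voom called 0 of the 24578 with enough reads (533, 768 and 1128). With circRNAs that share a back-splice end summed into sets, limma called 0 of 13955 sets (486). Of these sets 5701 held 2 or more circRNAs.

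**Figure D3:**
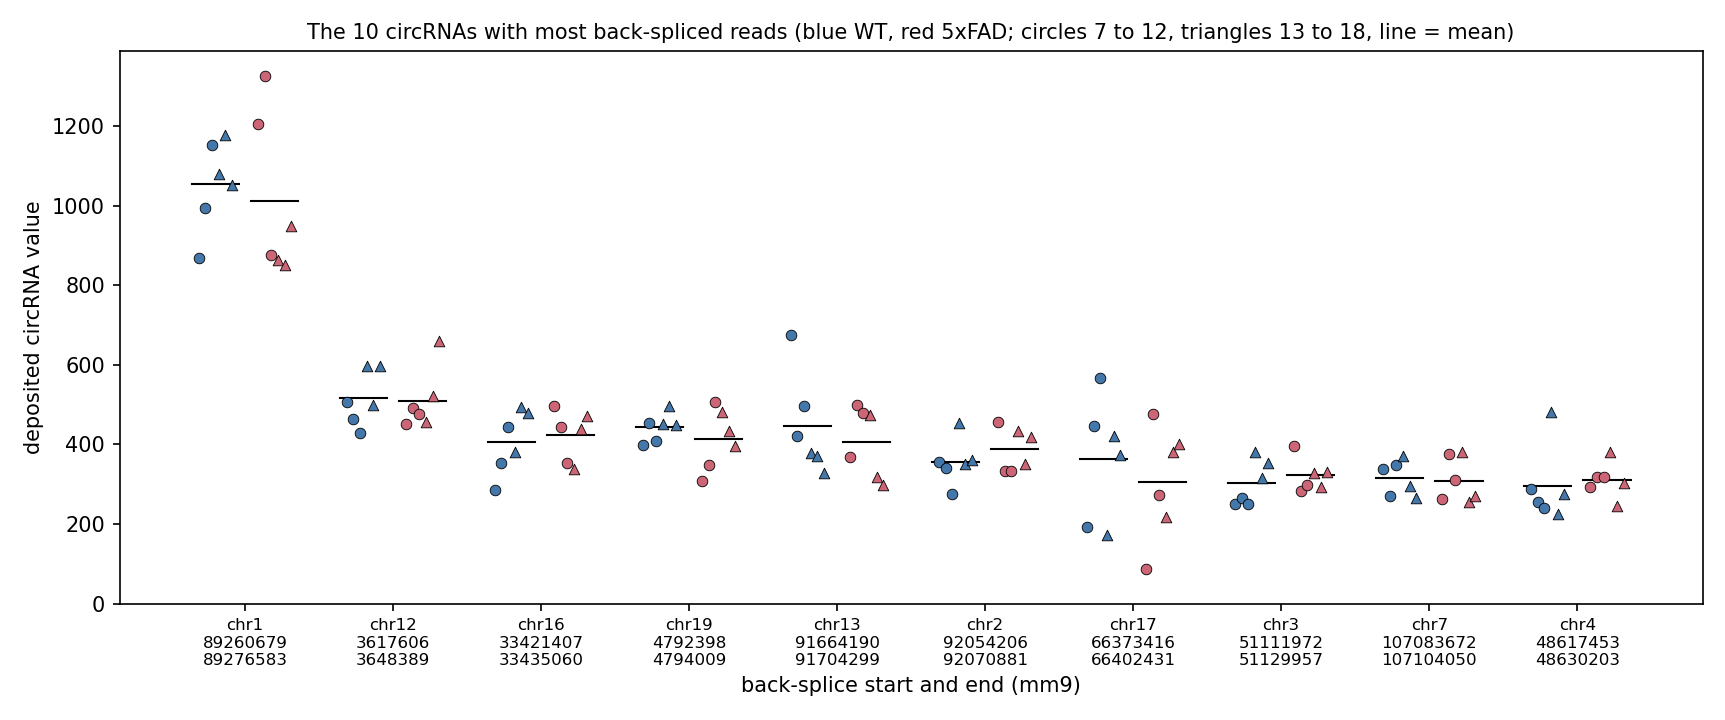
Normalized signal of the 10 most abundant circRNAs in each RNase R library, by genotype, with mm9 positions; circles are title numbers 7 to 12 and triangles 13 to 18. The most abundant measured 1053 in WT and 1011 in 5xFAD on average.

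Within run 7-12 the 5 circRNAs with the smallest p were all lower in 5xFAD and all lowest in the RNase R 5xFAD replicate 1. They lie at chromosome 6, 50093718 to 50113648, chromosome 16, 93847526 to 93853462, chromosome 1, 142259526 to 142279672, chromosome 2, 18206250 to 18230576 and chromosome 4, 126600308 to 126603267, with changes of -3.25, -2.40, -2.12, -2.08 and -2.53 (smallest adjusted p = 0.387). limma called 0 (1512 at an unadjusted p under 0.05), and edgeR, DESeq2 and voom 0 (607, 609 and 1567). Leaving out the RNase R 5xFAD replicate 2 gave 227 calls, replicate 3 gave 17 and WT replicate 1 gave 9.

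Within run 13-18 the circRNA at chromosome 5, 17814371 to 17814643 measured 4.00 ± 2.38 in WT and 0.557 ± 0.158 in 5xFAD (log2 -2.54, adjusted p = 0.173, n = 3 each). The circRNA at chromosome 12, 81279289 to 81282495 was listed at 0 in WT replicates 4 to 6 and measured 1.23, 1.39 and 1.79 in 5xFAD. Those at chromosome 2, 26772225 to 26773051 and chromosome 18, 46413933 to 46422611 had changes of -3.33 and -2.97. The circRNA at chromosome 5, 71397346 to 71405875 was listed at 0 in WT replicates 4 and 5 and measured 4.27 in replicate 6 and 4.62, 4.99 and 6.40 in 5xFAD. limma called 0 (1582 at an unadjusted p under 0.05), edgeR 0 (796), voom 0 (836) and DESeq2 the first 2 of these (858), with adjusted p = 0.0306 and 0.032. Both of these had a change of opposite sign in run 7-12, of 0.33 at chromosome 5 and of -0.81 at chromosome 12. The circRNA at chromosome 12 measured 1.16, 1.18 and 1.01 in WT replicates 1 to 3. For the difference between the runs limma called 0 (1566; smallest adjusted p = 1), as did edgeR (734), DESeq2 (797) and voom (1242), and across circRNAs the effects of the runs had r = -0.026. The circRNA at chromosome 19, 37671585 to 37683595 had a difference of 3.16, and the others among the 5 with the smallest p there are named above for a single run: chromosome 4, 126600308 (3.19), chromosome 5, 17814371 (-2.86), and those at chromosome 5, 71397346 and chromosome 12, 81279289 with values listed at 0.

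**Figure D4:**
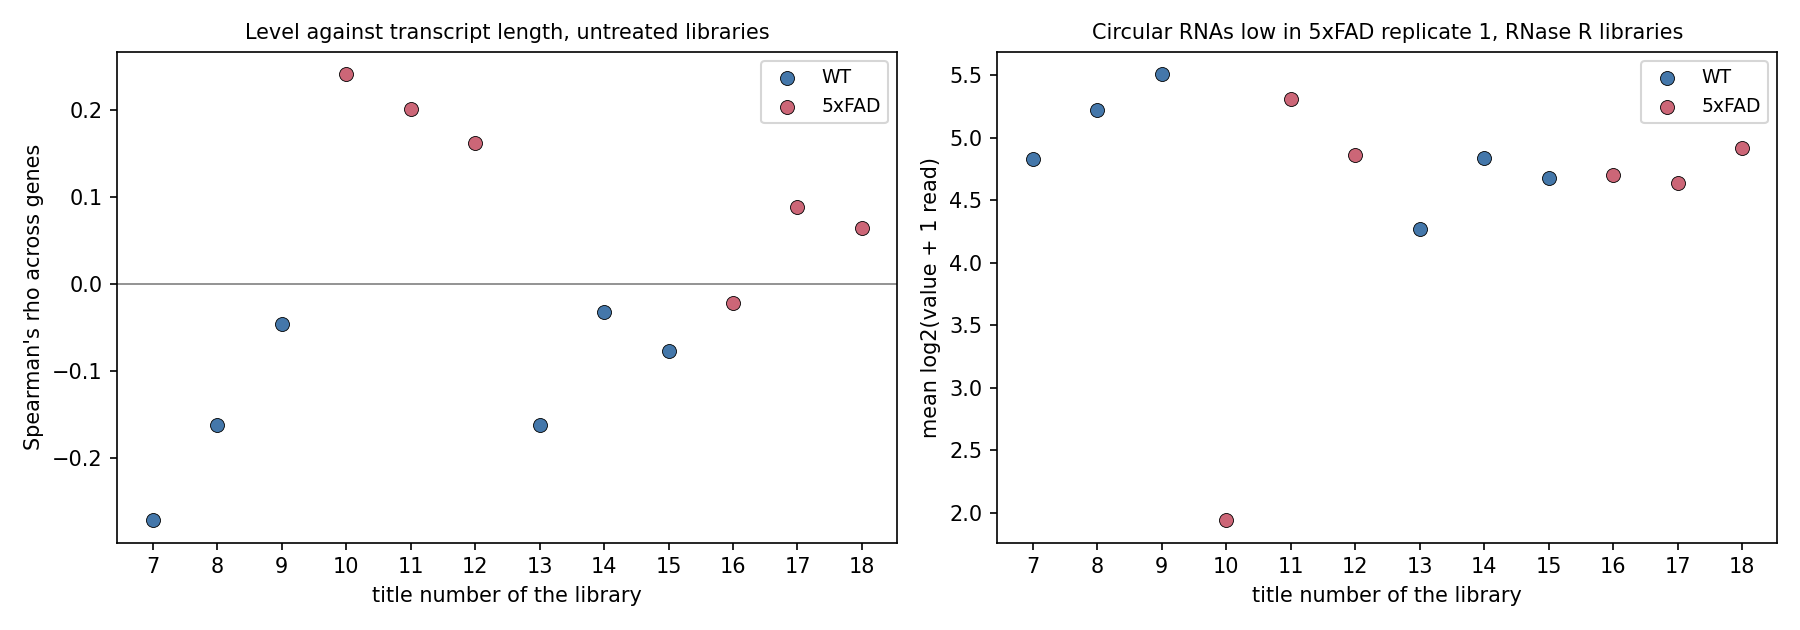
Left, Spearman's rho across genes between transcript length and relative level in each untreated library; right, mean log2(value + 1 read) of 78 circRNAs in each RNase R library, both by title number, with WT in blue and 5xFAD in red. The RNase R 5xFAD replicate 1 (title number 10) lies at 1.94 on the right, against 4.27 to 5.51 in the other libraries.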

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

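The tests of the 3 patterns weighed here (replicate 6, transcript length and the low circRNAs) were chosen only after the result was seen, and the tests for single far samples, for differences between runs and of chromosome Y reads were planned.

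Thy1 lay at 284 FPKM in the untreated library labelled 5xFAD replicate 6, far from 717 to 831 in the other 5. A swap with a WT library is argued against, since 0 WT libraries had Thy1 near those 5, and so is a library with few genes, since 17406 were above 0 in a range of 17270 to 17902; a carrier with a weaker immune response is argued against by Thy1 itself, at 284 FPKM against 286 to 332 in WT. Over 43 immune genes that part the other 5 from WT, its median position was 0.03 (quartiles -0.04 and 0.12, with 0 the WT mean and 1 the mean of the 5). This restates the WT levels of immune genes by which the library was noticed and is no separate support. A library of an animal without the transgenes would give such values, so the label may be wrong. The RNase R 5xFAD replicate 6 bears the same title number, 18, and was kept as labelled too. If both came from the same animal, the doubt extends to the circRNA comparisons. What stays open is the rest of the untreated library's profile. Bcl2a1b at 1.80 FPKM lay above every WT library, as did the other genes named as largest rises over both runs. The naming rule required this, so it is no separate support. Ly86 measured 8.867 FPKM against at most 7.165 in WT, and Clec7a 0.3006 against 0.1519. The margin was small for C4b (5.92 against 5.885) and Mpeg1 (7.618 against 7.555). Cst7 and Trem2, at 0.3376 and 6.768 FPKM, lay within the WT range. The 921 genes outside the immune lists called without this library had a median position of 0.41. On 500 genes ranked without the library being placed, it lay at 0.38, WT replicate 4 and 5xFAD replicate 4 at 0.71, the other WT libraries between -0.20 and 0.22 and the other 5xFAD libraries between 0.76 and 1.34.

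Longer transcripts were higher in libraries labelled 5xFAD. Spearman's rho between length and level, across genes within a library, averaged 0.122 ± 0.097 in 5xFAD and -0.126 ± 0.091 in WT (exact 2-sided permutation p = 0.00216, n = 6 each, the smallest that 924 splits can give), with 0.201 and -0.161 in run 7-12 and 0.043 and -0.091 in run 13-18 (exact permutation p = 0.1 each, the smallest possible). As the whole cause of the called genes the trend is argued against: with it removed, 203 of 369 called genes with a length were still called, the endothelial median of run 7-12 went from 0.64 to 0.62 and the respiratory chain median from -0.21 to -0.19. The calls lost may owe their size to it. Its source, in RNA quality, libraries or biology, stays open and was not tested.

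The RNase R library labelled 5xFAD replicate 1 had 78 of the 1000 most abundant circRNAs below 50% of the lowest other library, against 0 to 4 in other libraries. Low depth is argued against, since it held 1196931 back-spliced reads, and so is a lost stretch of 1 chromosome, since the 78 lie on 18 chromosomes. Their mean level also varied in the other 11 libraries, with an SD of 0.35 against a median of 0.08 and at most 0.14 in 1000 random sets, in line with circRNAs that share a sensitivity to a step of the treatment, which may have run further in this library. A biological variation of these circRNAs between animals was not tested and stays open.

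Single libraries lay far from their group in 26 cases of 300 groups tested, where chance gives about 5%. WT replicate 1 was highest in Ap1s1 (132.9 FPKM), Tmem261 (37.28), Ppp1r35 (11.32), Hist1h4a (119.3), 1810043H04Rik (36.18), Tpgs1 (39.98), Sst (386.6) and Btg2 (17.01), in its summed FPKM (572700) and in the share of that sum held by the small RNAs Rpph1 and Rmrp (34.24%). WT replicate 4 was highest in Osmr (1.031 FPKM) and Cd2ap (9.242). WT replicate 3 was lowest in Olig1 (27.46 FPKM) and highest in Prlr (2.825), Ttr (341.6) and Kl (6.583). 5xFAD replicate 2 was highest in Clic6 (4.2 FPKM), Ttr (169.1) and Kl (3.644), replicate 3 in H2-Q4 (13.88) and replicate 5 in Bdnf (11.99). Among circRNAs, WT replicate 3 was highest at chromosome 9, 43855868 to 43856381 (0.09184), WT replicate 4 at chromosome 4, 48617453 to 48630203 (481.3), 5xFAD replicate 2 at chromosome 6, 50093718 to 50113648 (47.79) and 5xFAD replicate 6 at chromosome 12, 3617606 to 3648389 (661.1).

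The effect of genotype differed between the runs for Malat1 and Rn45s, with fitted differences of -12.23 and 12.04 that rest on values listed at 0 and are no measured folds. It differed for the endothelial list (adjusted p = 1.28e-12), activity-regulated genes (7.47e-05), baseline astrocytes (0.0208), lysosome (0.0321) and myelin (0.0496). With an estimated correlation none of the 5 passed (adjusted p = 0.221 for endothelial genes and 0.95 for the others). Which lists differ depends on the untreated 5xFAD replicate 6. Without it the median difference was 0.40 for disease-associated microglia and 0.45 for complement (camera adjusted p = 2.17e-11 and 4.04e-07). With it the camera adjusted p was 0.394 and 0.491. An estimated correlation was not tried without this library.

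Back-spliced reads from chromosome Y entered the reported comparisons only as the term added afterwards. They were found in RNase R WT replicates 1 and 4 (374 and 181 reads) and 5xFAD replicates 3 and 4 (147 and 186 reads), with 0 in the other 8 libraries.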

How the results depend on the processing

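The term for chromosome Y reads, the removal of the length trend, the omission of genes listed at 0, the median-of-ratios scaling and the sets sharing a back-splice end for circRNAs, the thinning of libraries and the tests on recovered reads were chosen only after the data were seen. Of the alternatives for counts of calls, library totals and lists, 138 stayed within 1.5 times the value or on its side of the threshold and 59 did not; for single genes and circRNAs 2970 kept direction and side, 595 became weaker, 112 stronger and 47 reversed, and the cause was not tested unless stated. The count of 381 genes over both runs became 68 with no filter and 60 at 5 FPKM, 24 with quantile normalization, 2096 with array weights, 1479 with the chromosome Y term (1992 when 5xFAD replicate 6 was also left out), 230 with the length trend removed and 3 to 1033 without 1 library. The 645 of run 7-12 became 323 with quantile normalization, 2268 with array weights, 53 with the run alone (fewer libraries), 1939 with the chromosome Y term (1886 without replicate 6), 352 with the length trend removed and 15 to 428 without 1 library. The 2 genes of run 13-18 became 59 with the chromosome Y term and without replicate 6, 1 with the length trend removed, 0 without genes listed at 0 and 2 to 53 without 1 library. The 2 genes of the difference became 8 with array weights, 8 with the chromosome Y term, 1 with the length trend removed and 0 without genes listed at 0. The 10 lists called by camera became 0 with an estimated correlation. With fry the adjusted p over both runs was 0.0397 or 0.0411 for these lists, except 0.122 for antigen presentation and 0.0853 for risk orthologs. Within run 7-12 only the endothelial list passed by fry (adjusted p = 0.00687), and in run 13-18 the smallest was 0.15. The 0 circRNAs called by limma (1474 at an unadjusted p under 0.05 over both runs; 0 by edgeR and voom at the default filter) became, when detection in 3 libraries sufficed, 9 over both runs, 57 in run 7-12, 1 in run 13-18 and 21 for the difference. With the chromosome Y term and without replicate 6, 1 was called over both runs and 1 in run 13-18, where the run alone gave 1, edgeR from 2 reads gave 2 and DESeq2 gave 2. Without 1 library the counts ranged from 0 to 2 over both runs, 0 to 227 in run 7-12, 0 to 1 in run 13-18 and 0 to 70 for the difference. Log2 changes that reversed were, with quantile normalization, App (-0.053 to 0.065), Slc1a3 (-0.061 to 0.066), Neu4 (0.108 to -0.015) and the circRNA at chromosome 13, 91664190 (-0.118 to 0.026); with array weights, Atp1b2 (0.115 to -0.013), Ttr (0.542 to -0.243), Xist (0.289 to -0.633) and Uty (-0.048 to 0.46); with the length trend removed, Kdm5d (0.047 to -0.047); and with edgeR from 2 reads, the circRNAs at chromosome 16, 33421407 (0.072 to -0.011) and chromosome 4, 48617453 (0.111 to -0.005). Without 1 library the change ranged from -0.22 to 0.218 for Kl, -0.203 to 0.014 for Hbb-b1, -0.658 to 1.284 for Xist, -0.542 to 0.462 for Uty, -0.486 to 0.55 for Kdm5d and -0.699 to 0.736 for Eif2s3y, and for circRNAs from -0.079 to 0.039 at chromosome 12, 3617606, -0.019 to 0.158 at chromosome 16, 33421407, -0.525 to 0.046 at chromosome 17, 66373416 and -0.111 to 0.028 at chromosome 7, 107083672. Alternatives that need counts could not be run for genes, which have FPKM alone; comparisons of ages and of circRNAs with host genes were not run. No paired analysis was possible because WT and 5xFAD libraries share no title number. Precision limits the circRNAs: 4377 of 38535 had an interval that excluded a 2-fold change. The parts of depth and of spread between libraries in this were not tested.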

Other observations

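The gene families in this part and their tests were chosen only after the result was seen, and the tests on other splits of the libraries were planned.

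Genes of the mitochondrial respiratory chain were lower in 5xFAD cortex, in 75 of 75 tested members, with a median log2 change of -0.21 that was -0.12 with quantile normalization (camera adjusted p = 3.54e-24; adjusted p = 0.0579 with an estimated correlation). limma called 8 of them, among them Cox4i1, a subunit of cytochrome c oxidase, which fell from 614 ± 5.9 to 532 ± 29.7 FPKM (log2 -0.21, adjusted p = 0.0483), Ndufs8 and Cox7a2, which fell by 0.30 each, and Atp5f1, which fell by 0.29. Some of these calls led to the choice of the family. The median was -0.30 in run 7-12 and -0.15 in run 13-18.

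Histone genes had a median of -0.39 over 52 tested members, 48 of them lower (camera adjusted p = 1.67e-12; adjusted p = 0.0579 with an estimated correlation), and it was -0.38 with quantile normalization. With the length trend removed it was -0.34, and in run 7-12 it went from -0.53 to -0.39. The 9 called include Hist1h4c, which fell from 402 to 267 FPKM (log2 -0.60), Hist1h3g, which fell by 0.83, and Hist1h4f, which fell by 0.72. Ribosomal protein genes had a median of -0.13 over 78 members with 1 fall, which shrank to -0.01 with quantile normalization and turned to 0.01 with it in run 13-18 (camera adjusted p = 2.13e-11; adjusted p = 0.0587 with an estimated correlation). With the length trend removed it was -0.09, and in run 7-12 it went from -0.20 to -0.12. The median summed exon length was 0.54 kb for histone genes and 1.78 kb for ribosomal protein genes.

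A few long noncoding RNAs, picked from the calls after their values were seen, are given as single genes, and a set test of such genes was dropped for that reason. Meg3 rose from 291 ± 80.7 to 512 ± 106 FPKM (log2 0.84, adjusted p = 0.0399, n = 6 each), Neat1, a scaffold of nuclear paraspeckles, from 22.0 to 38.4 FPKM (log2 0.79), Snhg11 from 237 to 399 FPKM (log2 0.78), Kcnq1ot1 from 5.68 to 9.29 FPKM (log2 0.62) and Ftx by 0.48, while Miat at 0.86 did not pass (adjusted p = 0.0721). These rises were not separated from the trend with transcript length in the same libraries.

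For genes over both runs, 2 of 100 splits of the 12 libraries, the real one included, gave at least the 381 genes called. This share is under 0.05, but it cannot exclude chance, since structure apart from genotype can give more calls. The highest other split gave 880. That split parted title numbers 8, 9, 11, 14, 15 and 18 from 7, 10, 12, 13, 16 and 17 and gave 831 circRNAs as well, the highest for circRNAs over both runs, where the real split gave 0 and 100 of 100 gave as many. It points to a structure of the samples: all 4 libraries with chromosome Y reads lie on 1 side of it. With a term for the same 4 title numbers the real split gave 1479 genes. Chance cannot be excluded for the difference between runs, with 2 genes in the real split, reached by 13 of 100, and 1544 in the highest other, nor for that of circRNAs, with 0 and 781 (100 of 100). Within a run the 10 splits are too few for a share under 0.05: for genes the real split gave 645 and 2 and the highest other 0 and 0 (1 of 10 each), and for circRNAs it gave 0 and 0 and the highest other 473 and 3 (10 of 10 each). The 2 genes are Malat1 and Rn45s, whose values listed at 0 follow the real groups of run 13-18, so their count cannot bear on chance. Where the real split gave 0, every split gives as many, so those shares decide nothing.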
